A study of Mus musculus with 11 samples.

How the data were processed

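Total RNA of pooled oocytes or embryos was made into libraries with the SoLo RNA-Seq system, per the labels' protocols, and the values analysed were read counts per gene. The authors deposited whole-number counts for 24421 genes identified by Entrez number in 11 libraries, together with a width per gene that was not used. Per the submitters' processing notes, reads were mapped with STAR 2.5.0a, SAMtools was used and the genome build was GRCm38 (mm10). The counting program and its handling of strand and of reads shared between genes are not given in the sources used here. Values of overlapping or antisense genes and of near-identical copies are therefore uncertain. Gene symbols and GRCm38 coordinates came from a RefSeq gene table of the same build (GRCm38.p6), in which 24387 identifiers matched. The 34 unmatched identifiers held at most 0.032% of the reads of any library. No gene encoded by mitochondrial DNA was in the table.

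Libraries were grouped by the genotype and stage in the labels. Each library was 1 pool of 50 oocytes or embryos from 2 to 3 females, which the labels call 1 biological group. Only knockout females carried the Cre transgene, so the loss of Daxx and the transgene with its surroundings came together in every comparison of genotypes. A first replicate of the maternal knockout embryos was not analysed here. Total counts were 17978192 to 39798586 per library, so that a count of 0 allows at most 0.075 to 0.167 CPM (3 counts). These floors and the 95% counting intervals cover counting error only, since the libraries were amplified by PCR, per the labels' protocols, and no removal of duplicate reads is recorded in the sources used here. Count differences between replicates were checked with a chi-square statistic per degree of freedom, which lay between 5.10 and 37.2 for all pairs of a group, so no pair was treated as a duplicate.

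Levels are CPM, the deposited counts of a gene scaled by the library's total of counted reads, given as mean and SD over libraries. Tests used edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr with the groups (count minimum 10, total minimum 15), scaled with TMM factors and tested with the quasi-likelihood F test with robust dispersion estimates. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The SE of a log2 change is its size divided by the square root of F. The comparisons were knockout against control in oocytes (6 libraries), in 2-cell embryos (5 libraries), the difference of these effects (11 libraries in 1 fit), and control embryos against control oocytes (6 libraries). With 2 maternal knockout embryo libraries, the spread of that group rests mainly on what it shares with the controls.

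Before the data were examined, 31 gene lists, the comparisons, the alternatives and the rule for named genes were fixed. Lists with at least 5 tested genes were tested with camera (preset correlation 0.01), with limma 3.58.1, and again with an estimated correlation and with fry. The list of mitochondrially encoded genes had no gene in the table. The named genes were Daxx, the 10 largest rises and 10 largest falls among genes with adjusted p under 0.05, a mean of at least 10 CPM in the higher group and full separation of the libraries, leaving out predicted genes, pseudogene-type names and small RNAs. From each list that passed its test or held at least 3 genes that passed, up to 4 members with the smallest p were added. Where fewer than 10 genes passed, all of them and the 10 next by p were named. Other genes named in the text, such as the list members Sox2, Krt8, Bcl2l11, Map3k5 and Zfp68, were chosen after their values were seen. The same holds for Prm2 in oocytes and Gja1 between embryo genotypes, though the rule names both in another comparison. Some genes that the rule names are not reported here.

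Overlap of calls used Fisher's exact test among genes tested in both comparisons. For the embryo effect against the stage change, 100 sets of counts were simulated from the control means with gene-wise dispersions and no genotype effect. Alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, other low-count filters, a replicate block, all libraries in 1 fit and each library left out in turn. Runs without the genes of the chromosome 6 region, and the oocyte calls as sets in the embryo libraries, were added after the data were seen.

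The tests were checked on simulated counts with 200 changed genes per comparison. With gene-wise dispersions, the oocyte comparison (14076 genes) recovered 55.2% of 1.5-fold, 87.9% of 2-fold and 95.5% of 4-fold changes, and 11.7% of its calls were false. The embryo comparison (15201 genes) recovered 16.7%, 56.2% and 83.3%, with 17.7% of calls false. The difference between stages (16267 genes) recovered 6.35%, 43.8% and 69.4%, with 3.85% false, and the stage comparison (15149 genes) 40.0%, 64.6% and 96.9%, with 9.66% false. When dispersions followed the fitted trend, the share of false calls was 3.70%, 1.92%, 2.25% and 2.19% in that order. With gene-wise dispersions the share thus lay above the threshold of 0.05 in the oocyte, embryo and stage comparisons. There 21 of 179 simulated calls were false in oocytes and 22 of 124 in embryos. These shares depend on the 200 changed genes simulated. They do not carry over to the real data, with 83 calls in oocytes and 4 in embryos. Figures were drawn with matplotlib 3.10.9.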

Results

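The data set comprised 11 RNA-seq libraries from mouse oocytes arrested at metaphase of the second meiotic division (MII) and from 2-cell embryos. Daxx encodes a chaperone of the histone variant H3.3. In knockout females, floxed Daxx was deleted in growing oocytes by a Cre recombinase driven by the Zp3 promoter. Control females carried the floxed alleles without the Cre transgene, on a mixed background of C57BL/6J and 129/Sv. Oocytes were collected 20 hours after hCG. The 2-cell embryos were produced by in vitro fertilisation of such oocytes with JF1 sperm and collected 33 hours after fertilisation, so that embryos of knockout females lacked maternal Daxx but received a paternal allele. There were 3 control and 3 knockout oocyte libraries, 3 control embryo libraries and 2 maternal knockout embryo libraries. Each library held 50 oocytes or embryos pooled from 2 to 3 females. The oocyte libraries held 32582998 to 39798586 counted reads and the embryo libraries 17978192 to 25308468. Lars2, a gene known to collect reads resembling ribosomal RNA, took between 0.142% and 0.201% of the reads in the oocyte libraries. In embryos its share was 0.482%, 1.85% and 0.871% in control replicates 1, 2 and 3, and 1.81% and 0.552% in knockout replicates 2 and 3.

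Daxx itself, on chromosome 17 from 33909404 to 33915590 (GRCm38), was examined first. Levels are given in CPM, a gene's reads scaled to the library's total of counted reads. Control oocytes held 92.6 ± 5.67 CPM (SD, n = 3) and knockout oocytes 8.14 ± 0.286 (SD, n = 3), or 8.80% of the control level. The fall was -3.52 on the log2 scale (SE 0.07, edgeR adjusted p = 1.2e-11), and all 3 knockout libraries lay below all 3 controls. In 2-cell embryos the control level was 39.7 ± 6.14 CPM (SD, n = 3) and the maternal knockout level 24.2 ± 1.88 (SD, n = 2), or 60.8% of control. Both knockout embryo libraries lay below all 3 controls. The difference of -0.75 (SE 0.19) had an unadjusted edgeR p of 0.00081 for this gene, targeted by design. It did not pass when adjusted over all genes tested (edgeR adjusted p = 0.54). Over the alternatives that adjusted p ranged from 0.035, with all 11 libraries in 1 fit, to 1.00. The counts cover the whole gene, and the deleted part is not given in the sources used here. The knockout level in embryos was 297% of that in knockout oocytes, whereas the control level in embryos was 42.9% of that in control oocytes. These are shares of counted reads at each stage, not amounts per oocyte or embryo.

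**Figure D1:**
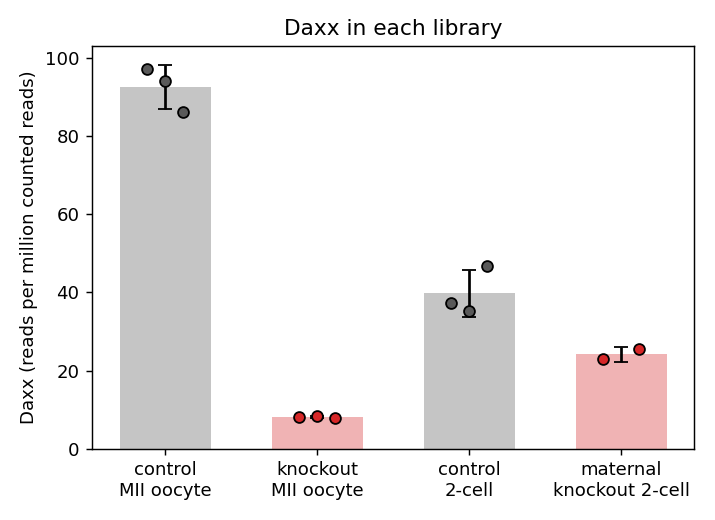
Daxx in CPM (vertical axis) in each library (points), with the group mean (bar) and SD (line), for control (grey) and knockout (red) oocytes and embryos. Knockout oocytes sat near 8.14 CPM, and knockout embryos at 24.2 against 39.7 in control embryos.

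The first comparison asked which transcripts differed in mature oocytes that had grown without Daxx. Of 14235 genes tested, 64 were higher and 19 lower in knockout oocytes, and 25 and 2 of these changed at least 2-fold. Brinp2, a gene of the nervous system on chromosome 1, rose from 2.14 ± 0.631 to 12.9 ± 2.51 CPM (log2 2.57, SE 0.21, edgeR adjusted p = 0.000901). The keratin gene Krt73 on chromosome 15 rose from 7.92 ± 2.72 to 34.8 ± 0.986 (adjusted p = 0.039). Its call was lost without control replicate 1 or 2, or knockout replicate 1, 2 or 3, and it passed in 8 of 14 alternatives (adjusted p from 3.2e-11 to 0.16). Drc1, which encodes a part of the ciliary dynein regulatory complex, rose from 3.66 ± 0.535 to 10.8 ± 1.45 (adjusted p = 0.00061), and Stox2 from 7.08 ± 0.892 to 15.3 ± 2.23 (adjusted p = 0.0033). The values are means ± SD of 3 libraries.

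Further genes that rose were Nefh, a neurofilament subunit (log2 0.95, SE 0.11), the receptor gene Notch1 (0.95, SE 0.17), the transcription cofactor gene Lmo4 (0.85, SE 0.15), the muscle myosin gene Myh2 (0.85, SE 0.15), the endothelin gene Edn1 (0.84, SE 0.11) and the cytokine gene Csf1 (0.71, SE 0.10), with edgeR adjusted p between 0.0052 and 0.049. Notch1 passed in 5, Lmo4 in 6, Myh2 in 7 and Csf1 in 9 of 14 alternatives. Apart from Daxx, the steepest fall was that of the transcription factor gene Foxp2 on chromosome 6, from 19.7 ± 0.563 to 8.53 ± 0.482 CPM (log2 -1.23, SE 0.09, adjusted p = 3.7e-05). Dsc3, a desmosomal cadherin gene, fell by 0.78 (SE 0.14) on the log2 scale, and Tnpo2, a nuclear import receptor gene, by 0.64 (SE 0.08). Falls below 0.5 on the log2 scale were called for Zfp940, the imprinted gene Peg3, the kinesin gene Kif5b, Tmem168, Efcab3, Ica1 and Thsd7a, of which Efcab3 passed in 2 of 14 alternatives and Tmem168 in 5 of 13. Foxp2, Tmem168, Ica1 and Thsd7a lie together on chromosome 6 between 8630527 and 15441977 (GRCm38), and 8 of the 81 calls with a known position, Daxx left out, started between 3372257 and 28828126 there. All 83 called genes separated the 3 knockout from the 3 control libraries, as 10% of genes would by chance. The number of calls depended on single libraries: it was 19 higher and 4 lower without control replicate 1, 16 and 5 without control replicate 2, 117 and 40 without control replicate 3, 41 and 12 without knockout replicate 1, and 34 and 15 without knockout replicate 3. It also depended on the test, with 153 higher and 70 lower in DESeq2, 45 and 12 in limma-voom, and 18 and 4 when all 11 libraries shared 1 fit.

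**Figure D2:**
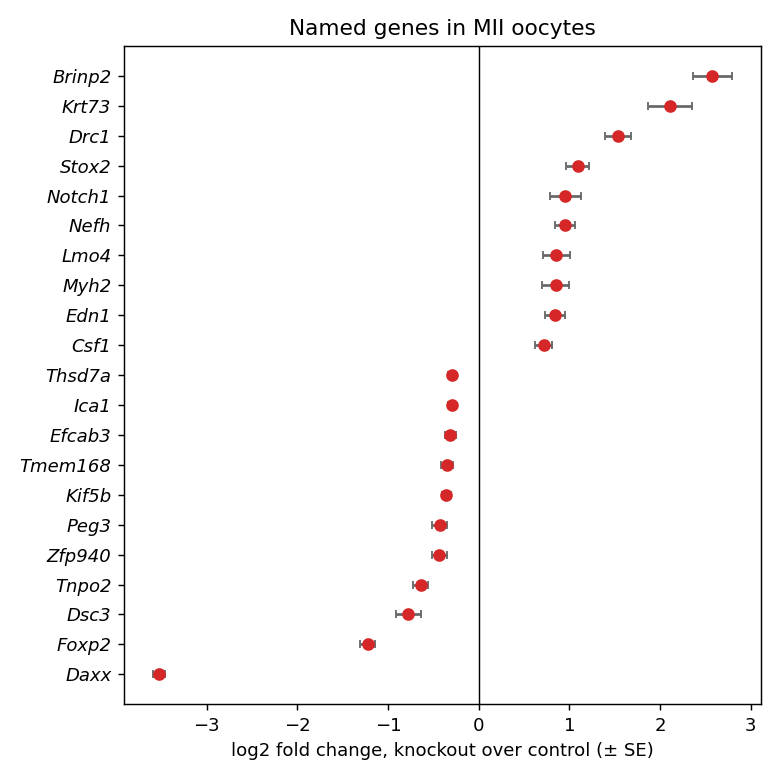
Log2 fold change of knockout over control MII oocytes (horizontal axis, points) with its SE (lines) for Daxx and the 20 genes named by rule. Daxx lay at -3.52, Foxp2 at -1.23 and Brinp2 at 2.57.

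By gene list, the oocyte changes were scattered. Of all 14235 genes tested, 1464 had an unadjusted p under 0.05, against 712 expected by chance. Of the oocyte-specific and maternal-effect genes, 0 of 58 passed the gene test. At an unadjusted p under 0.05 there were 11 such genes, DESeq2 called 2 and limma-voom 0. As a set they lay slightly lower (median log2 -0.04, camera adjusted p = 0.028), with adjusted p = 0.83 with an estimated correlation. Its members with the smallest p were Nlrp4e (-0.20, SE 0.05), Astl (0.31, SE 0.08), Nlrp9b (-0.15, SE 0.04) and Kpna7 (-0.30, SE 0.08), with edgeR adjusted p of 0.15 to 0.19. Among 30 genes of pluripotency and the first lineages, Sox2 rose from 1.97 to 4.19 CPM and Krt8 from 1.48 to 2.92 (2 genes also when adjusted over the list alone). Of 30 apoptosis genes, Bcl2l11 rose (log2 0.46) and Map3k5 fell (-0.24), also when adjusted over the list alone. Peg3 was the 1 imprinted gene of 44 that passed over all genes, and 4 imprinted genes were lower when adjusted over the list alone. At an unadjusted p under 0.05 there were 12 imprinted genes, 6 higher and 6 lower, while DESeq2 called 3 lower and limma-voom 1 lower. Of the numbered zinc finger genes 2 of 327 fell, Zfp940 and Zfp68, and 2 when adjusted over the list alone. None of 26 genes for H3.3, its chaperones and Daxx partners, 22 transient 2-cell genes, 50 genes of major zygotic genome activation, 25 DNA methylation genes or 47 heterochromatin genes passed the edgeR test, nor did any when adjusted over the list alone. At an unadjusted p under 0.05 these lists held 2, 4, 1, 3 and 4 genes in that order, and DESeq2 and limma-voom called 0 in each. Among markers of other cells, 0 of 12 granulosa and cumulus genes passed in edgeR (median log2 0.12), 2 were higher when adjusted over the list alone, 3 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0. By contrast 1 of 11 spermatid genes, Prm2, rose from 1.85 to 5.46 CPM. The spermatid list had adjusted p = 0.086 in camera and 0.83 with an estimated correlation, and passed fry, which tests whether its genes moved one way on balance (adjusted p = 0.0499).

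The second comparison asked whether embryos lacking maternal Daxx differed after the onset of zygotic transcription. Of 15414 genes tested, 4 were higher in maternal knockout embryos. Krt73 rose from 1.85 ± 0.843 (SD, n = 3) to 10.3 ± 1.67 (SD, n = 2) CPM, with a log2 change of 2.45 (SE 0.33, edgeR adjusted p = 0.011). The small nucleolar RNA gene Snord73b, which lies inside a ribosomal protein gene, rose from 7.06 to 22.4 (adjusted p = 0.011). Ap3b2, a neuronal adaptor protein gene, rose from 1.29 to 5.93 (adjusted p = 0.028), and Plekhh1 from 18.4 to 41.8 (adjusted p = 0.046). No gene was lower in edgeR, where 171 were lower at an unadjusted p under 0.05. DESeq2 called 1 lower gene and limma-voom 0. Across both directions 491 genes had an unadjusted p under 0.05, against 771 expected by chance. The 4 calls were lost without control replicate 1 and without control replicate 3, where edgeR called 0 genes and 497 and 611 had an unadjusted p under 0.05. Without knockout replicate 2, edgeR called 3 higher genes, of which 1 was among the 4, and without knockout replicate 3, 4 genes were lower. Of 13 alternatives, Krt73 passed in 10, Snord73b and Ap3b2 in 8 and Plekhh1 in 7, with adjusted p up to 0.29, 0.28, 0.51 and 0.60 in that order. When the 5 embryo libraries were regrouped across genotypes, edgeR called 17 genes with control replicate 1 and knockout replicate 2 against the others, and 5 with control replicate 2 and knockout replicate 2, the libraries with the highest Lars2 shares.

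The next 10 genes by p did not pass. They included Stc2 (log2 1.71, SE 0.31), Cttnbp2 (-1.05, SE 0.19), Tceal8 (1.42, SE 0.26) and Samd9l, each at edgeR adjusted p = 0.068. Samd9l had 2 reads in all control embryos and 45 in both knockout libraries, a ratio of 29.4 with a 95% counting interval of 7.68 to 250.3. The others were Nxph1, Sox6, Stox2, Fzd7, Brinp2 and Nefh, with adjusted p from 0.14 to 0.34. Cttnbp2, Samd9l and Nxph1 start within the same part of chromosome 6 as the oocyte calls.

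None of the gene lists had a member that passed in embryos in edgeR, DESeq2 or limma-voom, nor when adjusted over the list alone in edgeR, and the shifts of whole lists were small. Transient 2-cell genes, many driven by MERVL repeats, had a median log2 change of -0.004 over 54 members, of which 0 had an unadjusted p under 0.05 (camera adjusted p = 0.96). Replication-dependent histone genes had a median of 0.001 over 60 members (adjusted p = 0.86). With a preset correlation, 6 lists lay lower, namely ribosome assembly factors (median -0.14, camera adjusted p = 3.0e-09), ribosomal proteins (-0.20, 4.0e-07), splicing factors (-0.13, 0.00014), genes of major zygotic genome activation (-0.11, 0.00022), proteasome subunits (-0.11, 0.0017) and heterochromatin genes (-0.09, 0.034). Higher were maternal-effect genes (0.12, 0.0051), spermatid genes (0.11, 0.025) and Wnt and TGF beta signalling genes (0.12, 0.034). All 9 calls were lost with an estimated correlation, with adjusted p between 0.67 and 0.69. Of the 9 lists, 7, 8 and 6 were kept without control replicate 1, 2 and 3, and 3 and 5 without knockout replicate 2 and 3. The maternal-effect list turned lower without knockout replicate 3 (camera adjusted p = 0.73) and had adjusted p = 0.57 without control replicate 3. Examples were Ebna1bp2 (log2 -0.53, SE 0.15), Ncl (-0.35, SE 0.15), Rpl22 (-0.50, SE 0.21), Psmd6 (-0.52, SE 0.17), Oosp1 (0.42, SE 0.16) and Lef1 (0.54, SE 0.20), each with an edgeR adjusted p of 1.00 over all genes. Granulosa and cumulus markers had a median of 0.18 over 18 members (camera adjusted p = 0.060, and adjusted p = 0.67 with an estimated correlation).

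The genotype effects at both stages were then set side by side, in libraries that share no control. Of 13282 genes tested at both stages, 61 were called higher in oocytes and 4 in embryos. Only 1 gene, Krt73, was in both (0.018 expected, Fisher's exact test, two-sided, p = 0.018). Ap3b2 and Plekhh1, called in embryos, were not called in oocytes but separated the genotypes there in the same direction. Ap3b2 stood at 3.32 to 5.18 CPM in control and 7.52 to 12.8 in knockout oocytes. Plekhh1 stood at 20.2 to 24.7 and 28.2 to 42.1. Snord73b did not separate them, at 0.578 to 2.15 and 0.550 to 1.01. No gene was lower at both stages, since embryos had 0 lower calls in edgeR, 171 at an unadjusted p under 0.05, 1 in DESeq2 and 0 in limma-voom. Across genes, which are not independent replicates, Pearson's r of the log2 changes was 0.21 and Spearman's rho 0.13. With both effects from all libraries in 1 fit, over 17018 genes, these were 0.077 and 0.099. The oocyte calls were also tested as sets in the embryo libraries, a test chosen after the data were seen. Of the 61 genes higher in knockout oocytes, 57 were also higher in maternal knockout embryos, with a median log2 change of 0.56. The set passed camera (adjusted p = 2.7e-41), kept its call with an estimated correlation (adjusted p = 0.0028) and passed fry (adjusted p = 0.0030). Adjusted over the list alone, 21 of the 61 were higher in embryos, among them Brinp2, Krt73, Stox2, Nefh, Csf1 and Samd9l. That count was 14 without knockout embryo replicate 2 and 11 without knockout embryo replicate 3, Csf1 not among the latter, and 16 to 22 without a control embryo library. Drc1, by contrast, had a log2 change of 0.04 (SE 0.27) in embryos. Of the 18 genes lower in knockout oocytes, Daxx left out, 15 were lower in embryos (median -0.15, camera adjusted p = 0.0023). That call was lost with an estimated correlation (adjusted p = 0.33).

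**Figure D3:**
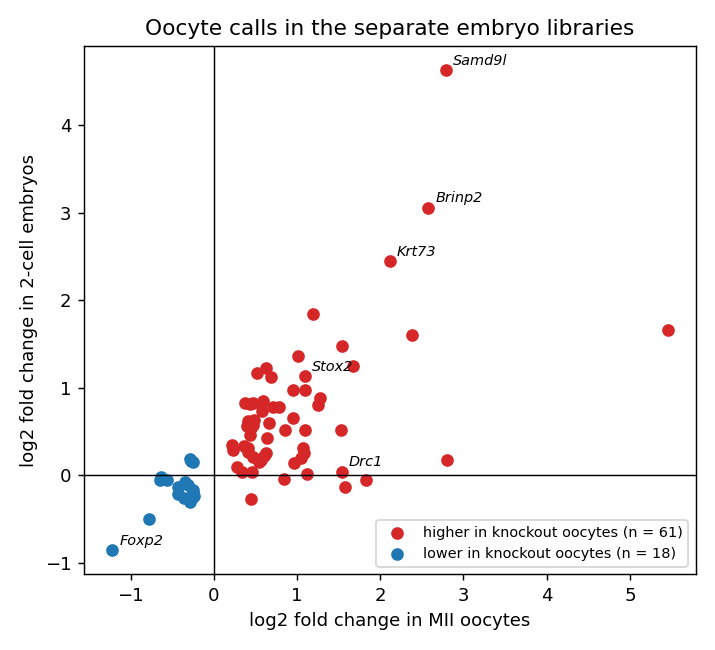
Fitted log2 fold change of knockout over control in MII oocytes (horizontal axis) and in 2-cell embryos (vertical axis) for genes called in oocytes, Daxx left out; each point is a gene. Of 61 genes higher in oocytes (red), 57 lay above 0 in embryos, and of 18 lower genes (blue), 15 lay below 0.

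The difference of the genotype effect between stages was tested across all 11 libraries. Of 17018 genes, 2 had a more positive effect in embryos, Daxx and Tceal8. The difference for Daxx was 2.76 on the log2 scale (SE 0.16, edgeR adjusted p = 3.4e-07). Tceal8, an X-linked gene of the elongation factor A-like family, stood at 98.5 ± 12.7 and 98.1 ± 11.3 CPM in control and knockout oocytes. In embryos it stood at 3.70 ± 0.375 and 10.2 ± 1.42, a difference of effects of 1.45 (SE 0.19, adjusted p = 0.014). No gene had a more negative effect in edgeR, with 490 at an unadjusted p under 0.05, whereas DESeq2 called 2 and limma-voom 1. For Drc1 the difference was -1.51 (SE 0.35) and for Tnpo2 0.61 (SE 0.15), both at adjusted p = 0.91. Further genes with the smallest p did not pass either, with Acer2 at -1.72 (SE 0.33), Nfkbiz at 0.74 (SE 0.17), Psmd6 at -0.58 (SE 0.14) and Wfs1 at 0.55 (SE 0.13), and with Gm10639, Card9 and Snord73b, at edgeR adjusted p from 0.57 to 0.91. Daxx passed in all 18 alternatives and Tceal8 in 12, with adjusted p from 1.1e-06 to 0.82. The call of Tceal8 was lost in limma-voom and without control oocyte replicate 1 or 2, control embryo replicate 2 or 3, or knockout embryo replicate 2.

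The last comparison described the passage from control oocytes to control 2-cell embryos. Its rises and falls are relative to the counted reads and do not measure amounts per oocyte or embryo. Of 15577 genes tested, 6708 were higher and 6231 lower in embryos, and 5139 and 4437 of these changed at least 2-fold. Several genes of the embryo had no read in any control oocyte library. The zinc finger gene Zfp352 stood at 290.0 ± 61.8 CPM in embryos (SD, n = 3), at least 10570-fold higher than the floor of 3 reads over the oocyte group. Pramel7 was at least 5839-fold higher, the homeobox gene Crxos at least 3975-fold, the potassium channel gene Kcnk6 at least 3258-fold and Tdpoz4 at least 3164-fold, by the same floor. Rab39, AA543401, Pramel6 and Fam43b were at least 2117-fold higher. Ubtfl1 had 2 reads in oocytes and 363.1 CPM in embryos, a ratio with a 95% counting interval of 5532 to 165030. Several of these genes, such as those of the Pramel and Tdpoz families, have close copies, and their counts are uncertain because the treatment of reads shared between copies is not given in the sources used here.

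The steepest falls were those of oocyte transcripts. Ftdc1 fell from 538.5 ± 25.9 to 5.65 ± 2.38 CPM (log2 -6.61, SE 0.24, edgeR adjusted p = 1.3e-09), and Pabpn1l, which encodes a poly(A)-binding protein, from 165.1 ± 5.52 to 2.98 ± 0.322 (log2 -5.82, SE 0.13). The oocyte linker histone gene H1f8 fell from 2197 ± 87.4 to 57.2 ± 6.57 (log2 -5.29, SE 0.12), and Glrx from 288.6 ± 15.2 to 7.46 ± 1.49. Dmac1, Dera, the respiratory subunit gene Ndufa8, Pdha2, Rnaset2a and Mfng fell by between 5.25 and 5.49 on the log2 scale. Daxx fell by 1.25 (SE 0.12, adjusted p = 9.2e-07).

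Among the gene lists, 45 of 53 transient 2-cell genes were higher and 7 lower, with a median log2 change of 7.86, or 7.81 with the 11 genes without oocyte reads at their bound. Examples were Pramel17 (0.326 to 177.7 CPM) and Tmem92 (0.906 to 135.0). Of 55 genes of major zygotic genome activation 42 rose, among them Obox3 (0.356 to 263.8) and Klf5 (0.401 to 91.2). Replication-dependent histone genes (49 of 57), ribosomal proteins (64 of 81), ribosome assembly factors (42 of 57) and genes of pluripotency and first lineages (25 of 35) were mostly higher, with Nop2, for example, going from 4.69 to 268.4. Conversely, 48 of 58 maternal-effect genes fell, among them Gdf9 (2529 to 187.7) and Tle6 (1180 to 76.5). Nuclear-encoded respiratory chain genes fell in 61 of 79 cases, as with Sdhd (88.5 to 3.65), and proteasome subunits in 25 of 36, as with Psma7 (212.2 to 8.26). DNA methylation genes were divided, with 9 of 26 higher and 12 lower, among them Dnmt1 (log2 -3.07, SE 0.09) and Uhrf1 (-2.66, SE 0.11) lower and Tet1 (4.48, SE 0.21) higher. Adjusted over the list alone, these counts were the same except for 8 higher maternal-effect genes against 7 over all genes. All 12 structural RNA and RNA quality genes were higher in embryos, Lars2 among them (1763 to 10663), as were 9 of 17 granulosa and cumulus markers, while 8 of those were lower. In camera 9 lists lay higher and 3 lower. With an estimated correlation no list passed in that comparison (smallest adjusted p = 0.26). All genes together had a median log2 change of 0.07, and of 0.17 with RLE size factors.

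**Figure D4:**
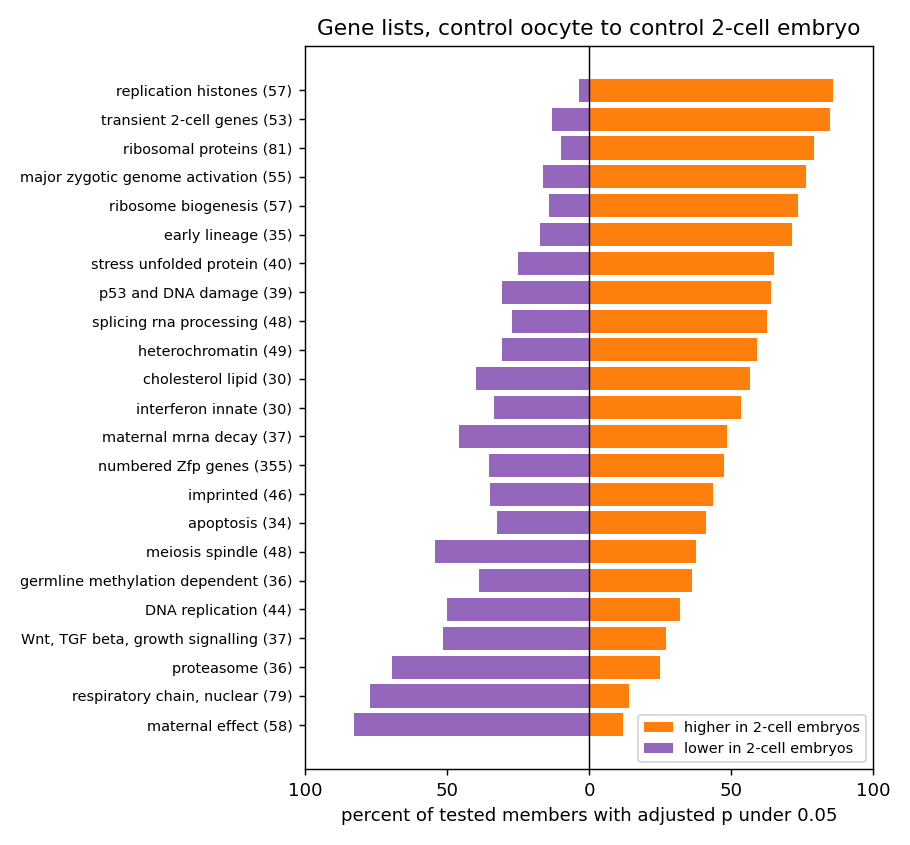
Percent of tested members of each gene list (number in brackets) that were higher (orange, right) or lower (purple, left) in control 2-cell embryos than in control oocytes at adjusted p under 0.05 (horizontal axis). Of 53 transient 2-cell genes 45 were higher, and of 58 maternal-effect genes 48 were lower.

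The embryo genotype effect was finally set against the stage change, a pair of comparisons that share the 3 control embryo libraries. Of 14969 genes tested in both, 6688 rose and 5778 fell between the stages. Of the 4 genes called in maternal knockout embryos, 1 was among the risers and 2 among the fallers, where independent lists would share 1.79 and 1.54. Across genes, which are not independent replicates, r between the genotype effect and the stage change was -0.18. In 100 simulations of unchanged knockout embryos against the same controls r averaged -0.047 (SD 0.009). The covariance was -0.158, against a simulated mean of -0.044 and a lowest simulated value of -0.064. With 3 control libraries no split leaves 2 on each side. When 2 of them entered the genotype effect and the other the stage change, r lay between -0.186 and -0.0191, so that it depended on the controls used. Part of the excess may come from the shared controls, whose variation along the stage axis the simulation did not include. Genes that fell between the stages had a median genotype effect of 0.11 and those that rose one of -0.02.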

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

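The tests of both explanations for Daxx, of the 30 Mb window, of the stage score, of the lists without 1 library and of the gene counts under other splits were chosen only after the result was seen.

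The genotype effect on Daxx differed between the stages by 2.76 on the log2 scale (edgeR adjusted p = 3.4e-07). Reads from an undeleted part of the maternal transcript would leave the same percent of control at both stages if shortened and full transcripts decayed alike. That was not measured. The lowest knockout embryo library stood at 57.5% of control and the highest knockout oocyte library at 9.07%, which argues against such reads only under that assumption. RNA of granulosa or cumulus cells stays open: 18 of 36 markers were tested in embryos, with a median log2 change of 0.18 (camera adjusted p = 0.060). The most abundant, Gja1, stood at 59.4 CPM in control and 67.8 in knockout embryos. In control oocytes Gja1 stood at 0.020 CPM, so its embryo level does not tell such RNA from transcription by the embryo itself. Transcription of the paternal allele after fertilisation, which the design provides, may account for the embryo level, a hypothesis that gene counts without alleles did not test.

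Of the 81 oocyte calls with a known position, Daxx left out, 8 lay within 25.5 Mb of proximal chromosome 6, among 74 tested genes. Chance placement stays open, since a permutation test drawing random tested genes of like expression gave p = 0.0267 for the densest window of 30 Mb, 0.0205 at 10 Mb, 0.0295 at 20 Mb and 0.164 at 50 Mb. In the separate embryo libraries, 9 of 63 genes of the region had an unadjusted p under 0.05. That was 14.3%, against 3.18% of genes elsewhere (Fisher's exact test, two-sided, p = 0.00018). The 63 include the 8 called genes by which the region was chosen, and genes are not independent replicates. Among the 55 genes that were not called, the genotype effects in oocytes and embryos had a rank correlation of 0.40 across genes. That was above the 0.35 that 95% of random sets stayed under. A haplotype or an insertion carried with the knockout in this region may therefore contribute, as may an effect of Daxx loss there, and the design does not separate them.

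The difference of effects between stages was also seen for gene lists in camera, with medians of -0.21 for genes of major zygotic genome activation, 0.15 for maternal-effect genes, -0.24 for ribosomal proteins, -0.16 for ribosome assembly factors, -0.21 for proteasome subunits and -0.13 for splicing factors (adjusted p between 7.4e-07 and 0.00068). All were lost with an estimated correlation (adjusted p = 0.52 to 0.56). Of the 9 lists that passed in embryos, 3 were kept without knockout replicate 2 and 8 without control replicate 2, and the maternal-effect list turned lower without knockout replicate 3 (camera adjusted p = 0.73), so a large part of 1 library in these shifts stays open. A slower passage to the embryo transcriptome may shift these lists and stays open. The stage score is the mean log2 level of genes that rose at least 2-fold between the stages minus that of genes that fell likewise. Its genes were chosen with the same control embryo libraries that are scored, which may favour high control scores. The score differed by -0.17 between knockout and control embryos, the direction of a slower passage. However, the higher knockout score (0.72) lay above the lowest control (0.63). The exact permutation p was 0.4, in a test that could not go below 0.1. With 10 splits of the 5 embryo libraries, too few for a share under 0.05, 4 gave at least the real 9 lists, and the highest other gave 10.

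Tceal8 differed between the stages by 1.45 on the log2 scale (edgeR adjusted p = 0.014), with 98.5 and 98.1 CPM in control and knockout oocytes and 3.70 and 10.2 in embryos, and passed in 12 of 18 alternatives (adjusted p from 1.1e-06 to 0.82).

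For the oocyte and stage comparisons 10 splits of 6 libraries are too few for a share under 0.05. In edgeR the real oocyte split gave 83 genes and the highest other 14, and the real stage split 12939 genes and the highest other 0. Thus 1 split of each reached the real count. Every other stage split mixed oocytes with embryos in both groups. A low count there was fixed in advance and says nothing about chance. In embryos the real split gave 4 genes and the highest other 17, from control replicate 1 and knockout replicate 2 against the others, and 3 of 10 splits gave at least 4. A mixed grouping thus gave several times the real count, for a reason that was not tested. For gene lists the real oocyte split gave 1 list and the highest other 7, with 8 splits giving as many. The real stage split gave 12 lists and the highest other 12, with 3 splits giving as many.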

How the results depend on the processing

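The runs without the genes of the chromosome 6 region were chosen only after the result was seen. No named value reversed under any alternative. Of 346 alternative values for genes named in oocytes, 256 kept their side of the threshold, 85 no longer passed and 5 newly passed. In embryos these were 586, 19 and 22 of 627, for the difference between stages 584, 6 and 2 of 592, and for the stage change 1869 of 1869 kept it. Brinp2, Daxx, Drc1, Stox2 and Tnpo2 passed in all 14 oocyte alternatives and Foxp2 in all 13 that tested it, while Efcab3 passed in 2 of 14, Notch1 in 5, Lmo4 in 6, Myh2 and Zfp940 in 7, Krt73, Dsc3 and Peg3 in 8, Csf1 in 9, Nefh in 11 and Edn1 and Kif5b in 13. Of 13 alternatives, Tmem168 passed in 5 and Ica1 and Thsd7a in 10. In embryos Krt73 passed in 10 of 13, Snord73b and Ap3b2 in 8 and Plekhh1 in 7, and for the difference between stages Tceal8 passed in 12 of 18. The cause was not tested where a count moved, except that the stricter filter tested 9385 genes in oocytes and leaving out a library leaves fewer samples.

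Counts of higher and lower genes in oocytes, 64 and 19 as reported, were 153 and 70 with DESeq2 (81 of the 83 calls shared), 130 and 53 without a low-count filter, 36 and 12 with a stricter filter, 45 and 12 with limma-voom, 18 and 4 with all libraries in 1 fit, and 54 and 11 without the chromosome 6 region. Leaving out 1 library gave 16 to 117 higher and 4 to 40 lower genes. In embryos, 4 and 0 as reported, they were 9 and 1 with DESeq2, 30 and 2 without a filter, 2 and 0 with limma-voom, and 12 and 1 with all libraries in 1 fit. Leaving out 1 library gave 0 to 5 higher and 0 to 4 lower genes, and an arm left with 1 library was assumed to vary like the other. For the difference between stages, 2 and 0 as reported, DESeq2 gave 2 and 2 and limma-voom 1 and 1, and leaving out 1 library 1 to 3 and 0 to 1. For the stage change, leaving out 1 library gave 6546 to 6933 higher and 5934 to 6269 lower genes.

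Gene lists passing in oocytes were 0 higher and 1 lower with camera, 0 and 0 with an estimated correlation, and 1 and 0 with fry (spermatid genes). In embryos 3 and 6 became 0 and 0 with an estimated correlation and with fry, as did 1 and 5 for the difference between stages. For the stage change 9 and 3 became 0 and 0 with an estimated correlation and 21 and 7 with fry. Calls shared between stages, 1 higher and 0 lower as reported, were 2 and 0 at adjusted p under 0.1, and 3 and 1 with both effects from all libraries in 1 fit.

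With the replicate number as a block, counts were 78 higher and 32 lower in oocytes, 1 and 1 in embryos (0 of the 4 calls shared), 2 and 0 for the difference between stages, and 6587 and 6177 for the stage change. In camera with that block, the embryo calls of heterochromatin genes (adjusted p = 0.49) and spermatid genes (0.28) were lost. Replication-dependent histone genes newly passed there as higher (adjusted p = 0.0053). Libraries with the same number did not clearly deviate together, with correlations of -0.108, 0.087 and 0.019 in oocytes and -0.102 and -0.025 in embryos. Values were centred within each group, so the 2 knockout embryo libraries mirror each other. With so few libraries, pairing by number was neither shown nor excluded. Depth limits genes near the floor of 0.075 to 0.167 CPM.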

Other observations

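The keratin genes, and the oocyte calls in embryos with their leave-one-out runs, were tested only after the result was seen.

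In oocytes, neighbouring keratin genes on chromosome 15 between 101733949 and 102004342 (GRCm38) were looked up after Krt73 was seen. Krt71 rose by 1.67 on the log2 scale (SE 0.24, edgeR adjusted p = 0.0096), beside Krt73 and Krt8. Krt72, at 1.12 (SE 0.32, adjusted p = 0.20), and Krt76, at 1.13 (SE 0.22, adjusted p = 0.056), did not pass, nor did Krt78 at 0.36 (SE 0.37, adjusted p = 0.82). The 4 tested keratin genes below that interval, between 101348315 and 101573904, did not pass either, with Krt80 at -0.01, Krt88 at -0.26, Krt84 at 0.05 and Krt75 at 0.35 (adjusted p from 0.49 to 0.99). Krt12, in another keratin cluster on chromosome 11, rose by 0.44 (SE 0.08, adjusted p = 0.028). The 6 other tested keratin genes there, with log2 changes from -0.07 (Krt25) to 0.41 (Krt20), did not pass (adjusted p from 0.78 to 0.97).

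A hypothesis is that part of the transcript changes of the knockout oocyte is also present in the 2-cell embryo. Of the 61 genes called higher in oocytes, 93.4% were higher in the separate embryo libraries, against 50.4% of all genes, and the set had adjusted p = 0.0028 with an estimated correlation. Without 1 embryo library 50 to 58 genes had that direction, with adjusted p from 0.0092 to 0.034 with an estimated correlation, and without the chromosome 6 region 53 of 57 did. The real split of the 5 embryo libraries gave a median log2 change of 0.56. Only 1 of 10 splits reached that size, too few splits for a share under 0.05. The largest other was -0.46, for control replicates 1 and 3 over the rest, a split that keeps both knockout libraries on the same side. Among splits that part the knockout libraries, the largest was 0.17, for control replicate 3 and knockout replicate 3 over the rest. Stored oocyte RNA, continued transcription in the embryo and a genetic difference carried with the transgene may each give this pattern, and these counts do not separate them.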
